A study of Drosophila melanogaster with 2 samples.

How the data were processed

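The samples were 2 biological replicates, numbered 1 and 3 per the labels, of whole Drosophila melanogaster embryos of both sexes. They came from a line that stably expresses Hr78 with eGFP at its C terminus. The embryos were aged 8 to 16 h per the source names in the labels. Chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the labels. Both replicates formed 1 group and came from the same donor line, so no comparison between groups and no paired analysis was possible.

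Per the text files deposited with the samples, peaks were called on each replicate's alignments with a control alignment, and again on both replicates together. An optimal list was made by thresholding on the irreproducible discovery rate (IDR). The caller, the aligner and the IDR threshold are not given in the sources used here. The peak signal, as deposited by the authors, is the caller's signal value against the control, and its scale differs between lists, so signals were compared by rank or within 1 list. The q-value was deposited as −log10 q and had a single value, 4.25, throughout the optimal list, so it was not used to rank peaks. The position of each summit was deposited by the authors as an offset in bp from the start of its region. Each replicate list and the pooled list held 30000 peaks, with median widths of 560 bp (replicate 1), 490 bp (replicate 3) and 530 bp (pooled). Median signals were 71.4, 57.1 and 118. The optimal list held 5723 peaks with signals from 271.7 to 22397 and a median of 441. All 5723 optimal peaks were the highest of the pooled list, with the same signal. Reads, signal tracks, the control and open chromatin were not analysed here. Read counts were not given, so the depth of each replicate is unknown. Intervals on shares therefore cover only the counting of peaks or genes.

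Coordinates were dm6, per the labels, and were compared with a reference of genome release 6 and Ensembl annotation release 115 (BDGP 6.54). No region extended beyond the end of its arm in any list. Peaks on the 6 arms 2L, 2R, 3L, 3R, 4 and X were used. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The random seed was 78. Adjusted p-values are Benjamini-Hochberg values within each family, the threshold was 0.05, and intervals on shares are 95% exact (Clopper-Pearson).

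Replicate overlap was the share of the 5723 highest-signal replicate 1 peaks that shared at least 1 bp with the 5723 highest of replicate 3, against 1000 random placements within arms. For the correlation, each optimal peak took the signal of the highest replicate peak that held its summit, or was nearest to it within 200 bp, and the interval came from 1000 bootstrap draws over peaks. Summits were assigned to 1 location class in the order of start-site window (500 bp), 5' UTR, coding sequence, 3' UTR, non-coding exon, intron and intergenic. Densities per arm have exact Poisson intervals, and the X ratio was tested with 100000 draws that placed peaks over the arms by length. Motifs were counted on either strand in windows of 101 bp around the summit and around a point 500 bp downstream, with an exact McNemar test over peaks. There were 21 consensus sequences and 27 arrangements of RGKTCA pairs, with spacers of 0 to 8 bases. Signals near and away from start sites were compared with 100000 permutations over peaks. For 23 gene lists, the share of protein-coding genes with an optimal summit within 1000 bp of a start site was compared with the other genes of the arms by Fisher's exact test.

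The lists were nuclear receptors, ecdysone response genes, ecdysteroid synthesis, tracheal genes, endoderm and midgut regulators, digestive lipases and sterol uptake, fat storage and fatty acid metabolism, glycolysis, oxidative phosphorylation, ribosomal proteins, DNA replication and cell cycle, Hox genes, segmentation genes, the Notch and Hippo pathways, markers of muscle, neurons, glia, hemocytes, fat body and germline, cuticle proteins, and odorant and gustatory receptors. Lists, motifs, tests, named-gene rule and 45 alternatives were fixed before the data were examined. For 13 list symbols the annotation's current symbol was looked up after a first pass over the lists, without the values of those genes. Gpat1 and ban had no match. The symbols dof and Lipin are older names of stumps and Lpin, which were already in the same lists, and each gene was counted once. Lists can share genes. The rule named the 25 optimal peaks of highest signal found in both replicates, by the protein-coding gene with the nearest start site. It also named up to 4 bound members of each list by signal, up to 3 further genes per location class, and Hr78. A few genes that the rule named are not reported here. Other genes, and list members given as not bound, were chosen after their values were seen.

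The tests were also run on simulated data. With 40% overlap planted, 42.0% was recovered, and with nothing planted the overlap had p = 0.279 (permutation test). With 200 motif copies planted, the excess of summits over flanks was 219 windows. With 1 repeat arrangement planted 1 was called, with no motif planted 0 were called, and with 0 or 1 gene list planted 0 and 1 were called. Alternatives covered the peak set, window sizes, backgrounds, gene assignment and each replicate alone. In the latter, the 5723 highest peaks of a single replicate replaced the optimal list. A further 25 alternatives were added after seeing the data, among them matching on number of start sites, 1 summit per region, and leaving out the higher-coordinate summit of pairs 150 to 250 bp apart. Start sites were matched in 5 classes, the highest holding all genes with 5 or more.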

Results

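Genome-wide binding of the nuclear receptor Hr78 was mapped by ChIP-seq in whole Drosophila melanogaster embryos of both sexes, aged 8 to 16 h. The embryos came from a transgenic line that expresses Hr78 fused at its C terminus to the green fluorescent protein eGFP, and chromatin was precipitated with an antibody against GFP. Hr78 belongs to the same receptor family as the vertebrate testicular orphan receptors, whose DNA-binding domains recognise the hexamer AGGTCA. The design held 1 group of 2 biological replicates, numbered 1 and 3. Without a second condition, the comparisons it allowed were between the replicates, and between bound places and the rest of the genome. Each replicate had a list of 30000 peaks, the pooled reads of both had another 30000, and an optimal list of 5723 reproducible peaks was drawn from these. The optimal list covered 2.58 Mb in 4939 distinct regions, of which some held several summits, so that 784 peaks repeated a region already listed. No file gave read counts, so the sequencing depth of each replicate is unknown. All positions are 1-based on release 6 of the genome (dm6).

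The highest peaks lay near the start sites of Syx17, rux and shi. Syx17 encodes a syntaxin of autophagosome fusion. Its summit, the first of the list, was at 3L:4403428, 59 bp from the nearest start site, with a signal of 22397 and rank 1 in both replicate lists. Next came rux, an inhibitor of cyclin A and its kinase, with a summit at X:6037376, 114 bp from the start site and a signal of 17731. The third was beside shi, the fly dynamin, at X:15891806, 310 bp from the start site, with a signal of 15488. An intergenic region on 2R from 13559737 to 13565059 held a pair of summits, 3181 and 4514 bp from the start site of CG13334, with signals of 11219 and 8089. Liprin-alpha, a synaptic scaffold protein, had a signal of 10035 at 2L:6723742.

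Other peaks among the 25 highest were at SCAP, Acsl, sturkopf and Cpr. SCAP, the escort protein of the sterol-regulated factor SREBP, had a summit 202 bp from its start site at 2R:6036590, with a signal of 7438. The intron of Acsl, which encodes a long-chain acyl-CoA synthetase, held a summit at 2R:8668813 with a signal of 7227. The lipid droplet protein gene sturkopf had a signal of 4786 at 3L:1313247, and its replicate ranks of 11 and 64 were farther apart than those of the others among the 25. Cpr, the cytochrome P450 reductase, had a signal of 4618 at 2L:6339321. The remaining peaks among the 25 were named by their nearest start sites: Rab19, Samuel, prd1, cbt (with 2 peaks, both within ush), qless, CG12824, RhoGEF3, comm, CG4615, GAPcenA, bic, CG3168, ps and CG5445. Their signals ran from 4552 at CG5445 to 7050 at Rab19. Hr78 itself was bound 32 bp from its start site at 3L:21496973, with a signal of 1504 and ranks of 203 and 496. The line carries a tagged copy of this gene, and whether that copy adds reads there was not tested.

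Most of the highest peaks were found in both replicates. Among the 5723 highest peaks of each replicate, the number in the optimal list, 85.7% of the replicate 1 peaks overlapped a replicate 3 peak by at least 1 bp. Random placement of the replicate 3 peaks within their chromosome arms gave a mean of 4.49% and a maximum of 5.61% in 1000 draws (one-sided permutation p = 0.001, the smallest possible). The share was lower by stricter criteria: 74.65% with 50% reciprocal overlap and 72.5% with summits within 100 bp. Of the replicate 3 peaks, 81.1% overlapped a replicate 1 peak. Where replicate 3 had a summit within 500 bp, the median distance between the replicates' summits was 32 bp (4954 summits). Of the optimal peaks, 99.1% were overlapped by a peak of each full replicate list and 83.0% by the 5723 highest peaks of both. Across 5656 optimal peaks with a signal in both replicates, Spearman's rho of log10 signal was 0.816 (95% bootstrap interval 0.803 to 0.828) and Pearson's r was 0.862. These correlations are across peaks, which are not independent replicates, and the optimal list had been chosen for reproducibility. Summits of the same region could take the same replicate signals, as both summits near CG13334 did, and the bootstrap drew them as separate peaks. With the nearest replicate summit within 200 bp, rho was 0.736 (0.720 to 0.752), below that interval.

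Peaks were concentrated at start sites and in introns and were scarce in coding sequence. Of the 5723 optimal summits, 2144 (37.5%) lay within 500 bp of an annotated start site, against a mean of 13.5% after random placement, a ratio of 2.79. Introns held 2590 further summits (45.3% against 39.2%) and intergenic sequence 750 (13.1% against 27.8%). Only 55 summits (0.961%) lay in coding sequence outside the start-site windows, where random placement put 13.7%. The share in 3' UTRs was also lower than random (72 summits, 1.26% against 4.38%). Each of these differences had p = 0.001, the smallest possible with 1000 placements (one-sided permutation test). Non-coding exons held 59 summits (1.03% against 0.759%, permutation p = 0.0120), and 5' UTRs beyond the start-site windows held 53 (0.926% against 0.776%, p = 0.0999), which did not pass the test. The call for non-coding exons was lost with 1 summit per region (permutation p = 0.162), without the higher-coordinate summits of pairs 150 to 250 bp apart (0.0619) and with start-site windows of 1000 bp (0.439). With windows of 250 bp the 5' UTRs passed too (2.04% against 1.32%, permutation p = 0.001, the smallest possible).

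Each class had strong examples. Besides the genes above, the highest peaks at start sites were those of CG46319, CG33523 and Mondo, a sugar-responsive transcription factor, with signals of 4537, 4386 and 4237. In introns they were those nearest COX7AL2, Past1 and CG18666 (signals 4452, 3643 and 3484), the last within the gene Samuel. Intergenic examples were nearest Rcd2, jigr1 and the rhodopsin gene Rh5, with signals of 3803, 3332 and 2777. In 5' UTRs the highest were in Pdp1, ex and CG7611 (3729, 2272 and 1995). The few summits in coding sequence were led by bif, the ubiquitin protease gene not, and RhoGAP18B (2454, 2322 and 1567). In 3' UTRs the highest were nearest CCT2, Tctp and puml (2255, 1825 and 1566), the first within CG7766. Examples in non-coding exons were nearest CG4004 and osa (1662 and 1409). Random placement ran over whole arms, and mappability was not taken into account.

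**Figure D1:**
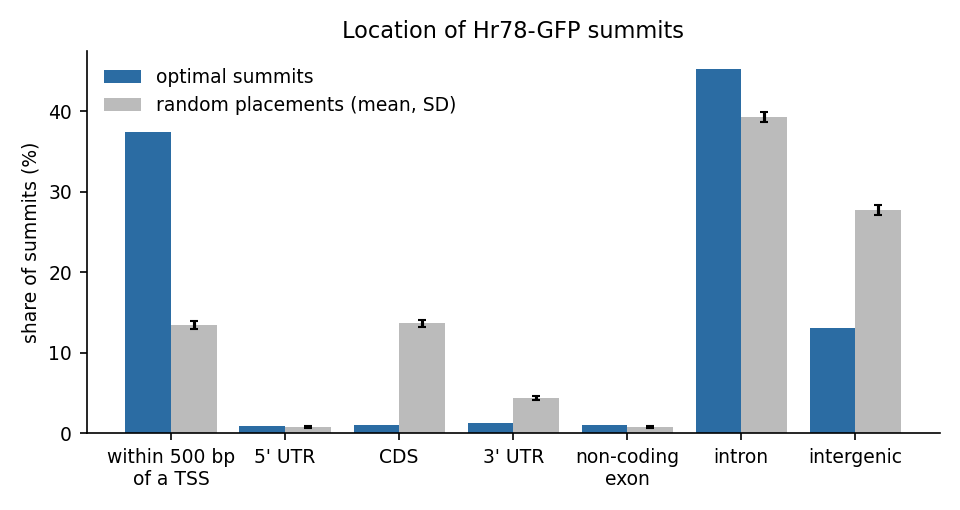
Share of the 5723 optimal summits in each location class (blue) beside the mean of 1000 random placements within chromosome arms (grey, bars 1 SD). Start-site windows hold 37.5% of summits against 13.5% at random, and coding sequence 0.961% against 13.7%.

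Peak density was lower on X than on the large autosomal arms together, and lowest on chromosome 4. On whole arm lengths there were 44.7 peaks per Mb on 2L (95% exact Poisson interval 42.1 to 47.5), 45.2 on 2R (42.6 to 47.9), 46.4 on 3L (43.9 to 49.0) and 40.1 on 3R (37.9 to 42.3). Chromosome 4 had 5 peaks, or 3.71 per Mb (1.20 to 8.66). On X the density was 39.7 per Mb (37.2 to 42.3), 0.904 times that of the 4 large autosomal arms (two-sided permutation p = 0.00405). The draws placed peaks independently, so this p-value does not cover variation among autosomal arms, of which 3R was close to X. The embryos were of both sexes, so X had fewer copies than the autosomes, which may lower its peak count. Within 500 bp of start sites the X to autosome ratio was 0.769 (305 peaks on X), and elsewhere it was 0.988 (629 peaks on X), both on whole arm lengths. With each arm's length taken only as the stretch spanned by peaks, there were 40.8 peaks per Mb on X (38.2 to 43.5), 46.03 to 50.3 on 2L, 2R and 3R, and 57.0 on 3L (54.0 to 60.2). On these lengths the X ratio was 0.815 for all optimal peaks (permutation p = 1e-05, the smallest possible), 0.693 near start sites and 0.890 elsewhere (permutation p = 0.00689). The ratios near and away from start sites differed (Fisher's exact test, two-sided, p = 0.000878). Annotated start sites were themselves less dense on X, with a ratio of 0.919 on whole arm lengths and 0.828 on the stretch spanned by peaks. On whole arm lengths the call on X did not hold in the higher-signal 2861 peaks (ratio 0.916, permutation p = 0.0739), in the peaks away from start sites (p = 0.794), or without the higher-coordinate summit of pairs 150 to 250 bp apart (0.931, p = 0.0569).

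The hexamer AGGTCA was enriched at Hr78 summits. It lay within 50 bp of the summit, on either strand, in 574 optimal peaks (10.03%, 95% exact interval 9.26 to 10.8), and in 152 windows of the same width centred 500 bp downstream (2.66%, 2.26 to 3.11). The difference was 7.37 percentage points (6.49 to 8.26) and the ratio 3.78 (exact McNemar test, two-sided, p = 9.92e-61). Peaks with higher signal carried it more often: 13.7% (12.0 to 15.6) of the 1430 highest and 6.92% (5.66 to 8.36) of the 1430 lowest (Fisher's exact test, two-sided, p = 2.69e-09). Peaks with the hexamer lay less often within 500 bp of a start site (30.3% of 574) than peaks without it (38.3% of 5149, Fisher's exact test, two-sided, p = 0.000189).

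Single sites lay close to several of the highest summits. At Liprin-alpha the hexamer was on the plus strand at 2L:6723729-6723734, within a start-site window and 10 bp from the summit. At prd1 it was on the minus strand at 3R:11786781-11786786, at Samuel on the plus strand in the intron at 2L:11058260-11058265, and at Acsl on the minus strand in the intron at 2R:8668824-8668829. At Syx17 a minus-strand copy at 3L:4403378-4403383 was 47 bp from the summit. The glycolytic gene Gapdh2 had a copy at X:15867956-15867961 and Mondo had one at 2L:21309786-21309791, both within start-site windows. No AGGTCA lay within 50 bp of the strongest summit at rux, shi, SCAP, Rab19 or Hr78.

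A second, smaller rise of the hexamer stood to one side of the summits. Per 1000 peaks there were 29.2 copies from 0 to 20 bp above the summit coordinate and 14.0 copies from 200 to 220 bp below it. In windows centred 210 bp toward lower coordinates 5.28% of peaks had the hexamer, and 210 bp toward higher coordinates 2.94% (exact McNemar test, p = 1.51e-10). Neighbouring optimal summits were often 150 to 250 bp apart: 844 such pairs had a median gap of 203 bp. In 838 of them the summit at the lower coordinate had the higher signal, and it carried AGGTCA in 15.2% of pairs against 5.21% for its partner (exact McNemar test, p = 1.80e-11). Without the 844 higher-coordinate summits, the share with AGGTCA within 50 bp was 10.9% of 4879 peaks. These measurements were chosen after the profile had been seen.

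**Figure D2:**
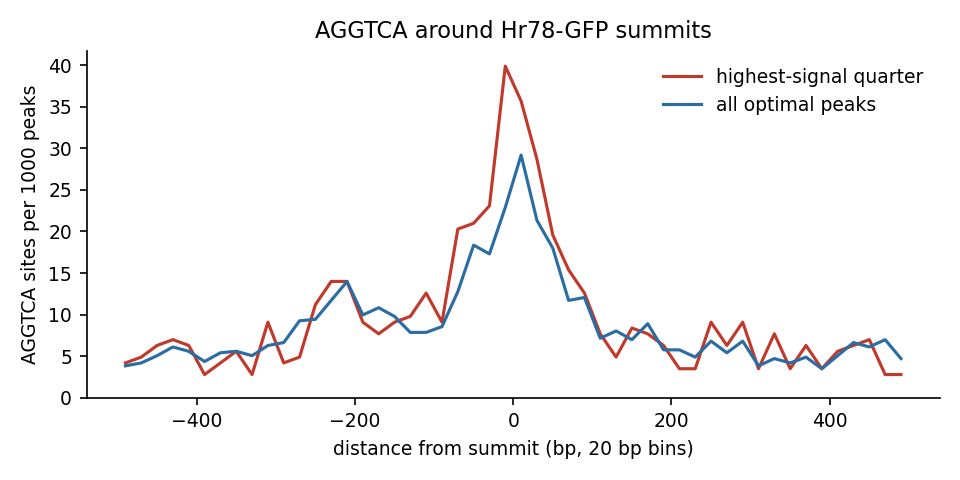
AGGTCA sites per 1000 peaks in 20 bp bins by distance from the summit, along the reference coordinate, for all 5723 optimal peaks (blue) and the 1430 of highest signal (red). The count is highest at the summit, and a smaller rise of 14.0 per 1000 stands from 200 to 220 bp toward lower coordinates.

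Pairs of hexamers were most often direct repeats with a spacer of 1 base. With the degenerate hexamer RGKTCA (R is A or G, K is G or T), this arrangement, DR1, occurred within 50 bp of the summit in 78 peaks and in 2 flanking windows (exact McNemar test, p = 5.36e-21, adjusted p = 1.45e-19 over 27 arrangements). DR2 was found in 20 peaks against 1 flank (exact McNemar adjusted p = 0.000283), DR0 in 19 against 1 (0.000361) and DR4 in 18 against 1 (0.000515). DR8, with 13 against 2, and DR3, with 8 against 0, passed with exact McNemar adjusted p = 0.0352 each. DR6 (10 against 2, exact McNemar adjusted p = 0.149), DR5 (4 against 1) and DR7 (3 against 0) did not pass, and no inverted or everted repeat occurred in more than 4 peaks. Several of these calls depended on the peak set. DR3 was lost with either replicate left out (exact McNemar adjusted p = 0.121 without replicate 1 and 0.141 without replicate 3), and DR8 in the 2861 highest peaks (0.101). DR6 was called without replicate 1 (exact McNemar adjusted p = 0.0211) and with 1 summit per region (0.0452). In all, 162 peaks had a direct repeat with a spacer of 0 to 8 bases. Single RGKTCA hexamers were themselves more frequent within 50 bp of summits (30.3% of peaks) than in flanks (12.1%). Pairs can therefore exceed flanks without a preferred spacing, which the tests against flanks do not separate. Density alone would raise the arrangements about alike. DR1 lay in 1.36% of summit windows (exact interval 1.08 to 1.70), and DR2, the next, in 0.35% (0.21 to 0.54). DR5, DR7 and each inverted or everted repeat had at most 4 peaks. For DR1 these counts argue against density as the whole cause. The weaker calls, such as DR3 with 8 peaks, may reflect the density of single hexamers alone. With AGGTCA required in both hexamers, only DR1 passed of the 27 arrangements. DR0 and DR2 then occurred in no summit window, and DR4 in 2.

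There were 90 DR1 sites in the 78 peaks. The upstream hexamer was GGGTCA in 41 sites (45.6%, 35.0 to 56.4), against 27.8% of all 2166 RGKTCA sites in summit windows. The spacer was G in 38 (42.2%) or A in 31 (34.4%). The downstream hexamer was AGGTCA in 33 (36.7%, 26.8 to 47.5) or AGTTCA in 32 (35.6%, 25.7 to 46.4), and both intervals include the shares of these forms among all sites, 28.1% and 29.9%. The following sites were taken from the DR1 peaks of highest signal after these had been seen. The SCAP promoter carried GGGTCACAGTTCA at 2R:6036612-6036624. GGGTCAGAGGTCA stood in a 3' UTR near CCT2 at X:9094063-9094075 and within a start-site window of Asator on chromosome 4 at 488889-488901. An intron of neur, the ubiquitin ligase of Notch signalling, held AGGTCACAGGTCA at 3R:9027199-9027211. The intron of baz, a cell polarity gene, held GGGTCAGAGTTCA on the minus strand at X:17173189-17173201.

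**Figure D3:**
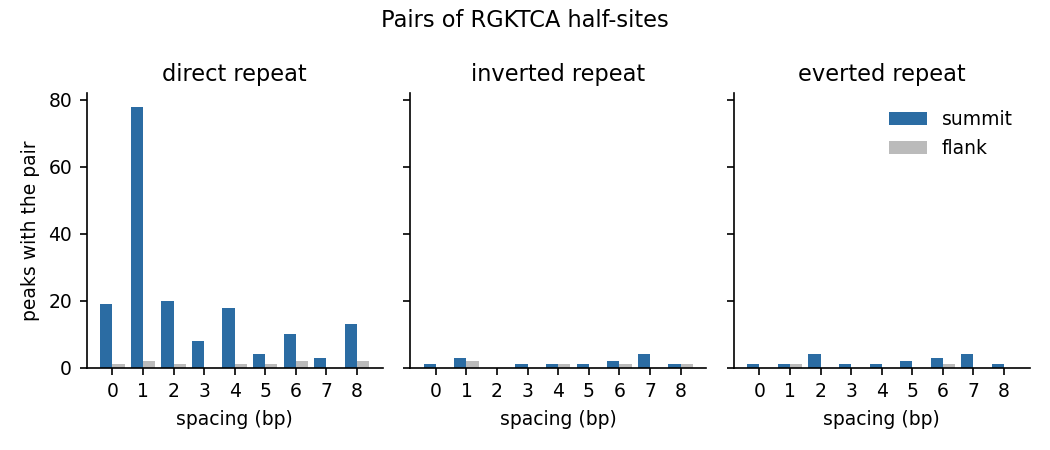
Number of optimal peaks with a pair of RGKTCA hexamers within 50 bp of the summit (blue) and in flanking windows 500 bp downstream (grey), by orientation and spacing in bp. The direct repeat with spacing 1 stands highest, with 78 peaks against 2 flanks.

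GATA and BEAF-32 motifs were also more frequent at summits than in flanks. Of 21 consensus sequences tested, AGGTCA included, WGATAR (the GATA factor motif) occurred in 24.2% of summit windows against 19.3% of flanks (exact McNemar adjusted p = 2.52e-09). CGATA, the motif of the insulator protein BEAF-32, occurred in 14.2% against 11.2% (exact McNemar adjusted p = 5.35e-06). This short sequence also lies within the DREF motif TATCGATA, so the counts of these motifs overlap. The CTCF core motif (4.51% against 3.39%, exact McNemar adjusted p = 0.0138) and a CA repeat (3.79% against 2.92%, adjusted p = 0.0417) also passed. Both of these calls were lost with flanks taken upstream (exact McNemar adjusted p = 0.0580 and 0.141) and without the higher-coordinate summits of close pairs (0.0587 and 0.265). The CTCF call was also lost without replicate 1 (exact McNemar adjusted p = 0.209) and the CA repeat without replicate 3 (0.699). The other 16 consensus sequences did not pass. They included the DREF motif (0.577% against 0.280%, exact McNemar adjusted p = 0.0745), the GAGA factor motif (2.81% against 2.18%, adjusted p = 0.107) and the extended monomer site TCAAGGTCA (12 peaks against 6, adjusted p = 0.416). Zelda, M1BP, Su(Hw), TATA, both E-box forms, Grainy head, POU, Mef2, Trachealess, homeodomain, Pho and ETS consensus sequences made up the rest, with exact McNemar adjusted p from 0.176 to 1. In the 5723 highest peaks of either replicate alone, the GAGA motif (exact McNemar adjusted p = 4.86e-05 in replicate 3 and 0.0349 in replicate 1) and the DREF motif (0.0405 and 0.0449) were called. M1BP was called in replicate 3 alone (exact McNemar adjusted p = 0.00654) and the extended monomer site in replicate 1 alone (0.0446).

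Peaks near start sites had slightly higher signal than the others. The median was 468 in the 2144 peaks within 500 bp of a start site and 428 in the other 3579, a ratio of 1.10 and a difference of 0.0394 on the log10 scale (two-sided permutation test over peaks, p = 1e-05, the smallest possible). Without replicate 1, the 5723 highest peaks of replicate 3 alone gave a difference of 0.0224 (permutation p = 0.00117). Peaks are not replicates, and the signal is the caller's own scale.

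Glycolytic genes and genes of fat storage and fatty acid metabolism were bound far more often than other genes. A gene was counted as bound when an optimal summit lay within 1000 bp of any of its start sites, which held for 2298 of 13945 protein-coding genes (16.5%). Of 15 genes of the glycolysis list 11 were bound (73.3%, 95% exact interval 44.9 to 92.2, adjusted p = 1.30e-05, Fisher's exact test, two-sided, over 23 lists). The strongest were Gpdh1, glycerol-3-phosphate dehydrogenase (signal 3362, 2L:5944836, in an intron), Ald1, aldolase (2933), Gapdh2 (2009) and Eno, enolase (1381). Hex-C, Pgi, PyK and Gpo1 were not bound. Gpdh1 and Gpo1 act in the glycerol-3-phosphate shuttle and not in glycolysis itself, and without them 10 of 13 genes were bound (76.9%, 46.2 to 94.96, Fisher adjusted p = 1.96e-05). Of 30 fat metabolism genes 19 were bound (63.3%, 43.9 to 80.1, Fisher adjusted p = 1.85e-07). They were led by SCAP (7438), Mtp, the microsomal triglyceride transfer protein (2940), ATPCL, ATP citrate lyase (1545), and Lsd-2, a perilipin of lipid droplets (1446). SREBP, the partner of SCAP, and the lipase gene bmm were not. Both lists were still called against random lists matched on gene length and number of start sites (permutation adjusted p = 0.0110 for glycolysis and 0.00153 for fat metabolism). Lists matched in this way had mean bound shares of 33.7% for glycolysis and 29.3% for fat metabolism, well above the 16.5% of all genes. Gpat4, of the fat list, shares its summit with yki of the Hippo list.

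Nuclear receptor genes and ecdysone response genes were bound more often than others. Of 21 nuclear receptor genes 12 were bound (57.1%, 34.0 to 78.2, Fisher adjusted p = 0.000152). The strongest were Hr39 (signal 3348, 2L:21237579, 329 bp from its start site), svp, the COUP-TF orthologue (2055), Hr78 itself (1504) and Eip75B (1111). The ecdysone receptor gene EcR was bound (402) and that of its partner usp was not. Of 29 ecdysone response genes 11 were bound (37.9%, 20.7 to 57.7, Fisher adjusted p = 0.00951), among them Hr39, Eip75B, Sox14 (1454) and tai (818), a coactivator of the ecdysone receptor. Hr39, Eip75B, Hr4, EcR, ftz-f1 and Hr3 are bound members of both lists. Of 17 genes of ecdysteroid synthesis and metabolism 2 were bound, Npc2a (829) and mld (326), and the list did not pass (11.8%, Fisher adjusted p = 1). Against random lists matched on gene length the nuclear receptors were called (permutation adjusted p = 0.0230) and the ecdysone response genes were not (0.232). With the number of start sites also matched, neither was called (0.0644 and 0.795).

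Several developmental lists were also bound more often. The Notch list had 9 of 21 genes bound (42.9%, Fisher adjusted p = 0.00951), including E(spl)m7-HLH (signal 1170), neur (1010), E(spl)mdelta-HLH (993) and E(spl)m2-BFM (970). The genes of the receptor N and of its ligands Delta and Ser were not bound. Many genes of the Notch list belong to the E(spl) complex. The list tests counted genes as independent, although neighbouring genes can share a peak. In the Hippo list 8 of 15 genes were bound (53.3%, Fisher adjusted p = 0.00380), led by ex (2272), dachs, an atypical myosin (1268), ds (645) and Diap1 (636). The gene of the effector yki and its partner sd were bound too (322 and 321), and the kinase genes hpo and wts were not. Glial genes were bound in 6 of 11 cases (54.5%, Fisher adjusted p = 0.00951), with moody, a receptor of the blood-brain barrier (1954), Gli (749), gcm2 (689) and nrv2 (541). The glial regulators repo and gcm were not bound. Of 34 tracheal genes 14 were bound (41.2%, Fisher adjusted p = 0.00209), among them crb (2076), Pvr (1067), stumps (865) and trh (667), the regulator of tracheal fate. Muscle genes were bound in 7 of 18 cases (38.9%, Fisher adjusted p = 0.0343), with Msp300 (2035), Mef2 (890), kon (672) and Tm1 (541). Of these 5 lists, only Notch was still called against random lists matched on length (permutation adjusted p = 0.0445) and on length and number of start sites (0.0103). The others then had permutation adjusted p from 0.108 to 0.516 on length and from 0.0891 to 1 on both. The Hippo and tracheal calls were also lost among the 2861 highest peaks (Fisher adjusted p = 0.105 and 0.123), and the Hippo and glial calls with a 500 bp window (0.0699 and 0.0789).

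Ribosomal protein genes were bound more often, and 3 lists less often. Of 92 ribosomal protein genes 30 were bound (32.6%, 23.2 to 43.2, Fisher adjusted p = 0.000804). RpS28a and RpS21 had signals of 3908 and 3906, and RpL19 had 603. Most of their peaks were of low signal: among the 2861 highest optimal peaks the bound share was 7.61%, no longer above that of other genes (Fisher adjusted p = 0.810). The call was also lost when each peak was given only to the gene with the nearest start site (Fisher adjusted p = 0.0733). It was kept against random lists matched on length (permutation adjusted p = 0.00115, random mean 10.7%) and on length and number of start sites (0.00153, random mean 16.2%). Oxidative phosphorylation genes were bound in 6 of 90 cases (6.67%, 2.49 to 14.0, Fisher adjusted p = 0.0184), namely COX7AL2 (4452), ND-ASHI (545), ND-51 (379), ATPsynG (322), ATPsynE and ND-42. Cuticle protein genes were bound in 8 of 120 cases (6.67%, 2.92 to 12.7, Fisher adjusted p = 0.00547). The first of them by signal, Cpr (4618), is cytochrome P450 reductase and not a cuticle protein. Without it the count was 7 of 119 (5.88%, Fisher adjusted p = 0.00240), with Cpr62Ba (852), Cpr65Ay (682) and Cpr67Fa1 (414) the highest. A single odorant or gustatory receptor gene of 119 was bound, Or88a (signal 575), a share of 0.840% (0.0213 to 4.59, Fisher adjusted p = 1.85e-07). Against random lists matched on length, the oxidative phosphorylation and cuticle lists were not called (permutation adjusted p = 0.411 and 0.392), and the receptor list was (0.00115).

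The remaining lists did not pass the test. Fat body genes were bound in 4 of 12 cases (svp, Adh, Apoltp and srp, Fisher adjusted p = 0.199), and endoderm and midgut regulators in 5 of 16, led by Hnf4 (916), bowl (717), GATAe (567) and srp (476) (Fisher adjusted p = 0.253). The latter list was called without replicate 1 (43.8% bound, Fisher adjusted p = 0.0221). Segmentation genes were bound in 4 of 21 cases (hry, en, ptc and gt, Fisher adjusted p = 0.882), germline genes in 2 of 12 (gcl and nanos, Fisher adjusted p = 1) and replication and cell cycle genes in 6 of 36 (Fisher adjusted p = 1). In that last list CycE (611), Dp (468), Dref (421) and E2f1 (389) were the highest, and Dref shares its summit with RpL13. A single hemocyte gene of 12 (srp), neuronal gene of 16 (elav, signal 1431) and gene of digestive lipases and sterol uptake of 18 (Lip4, 775) was bound (Fisher adjusted p = 0.852, 0.635 and 0.489). None of the 8 Hox genes had a summit within 1000 bp of a start site (upper 95% exact limit 36.9%, adjusted p = 0.498). When each peak was given to the gene with the nearest start site at any distance, 7 of the 8 were bound (87.5%, Fisher adjusted p = 0.000294), as were 11 of the 16 endoderm and midgut regulators (68.8%, Fisher adjusted p = 0.000141) and 6 of the 12 fat body genes (Fisher adjusted p = 0.0341). Start sites of neighbouring genes can share a peak, and genes with more start sites have more chances to be counted as bound. The counts by nearest start site at any distance were not matched on gene length or on distance to neighbouring genes.

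**Figure D4:**
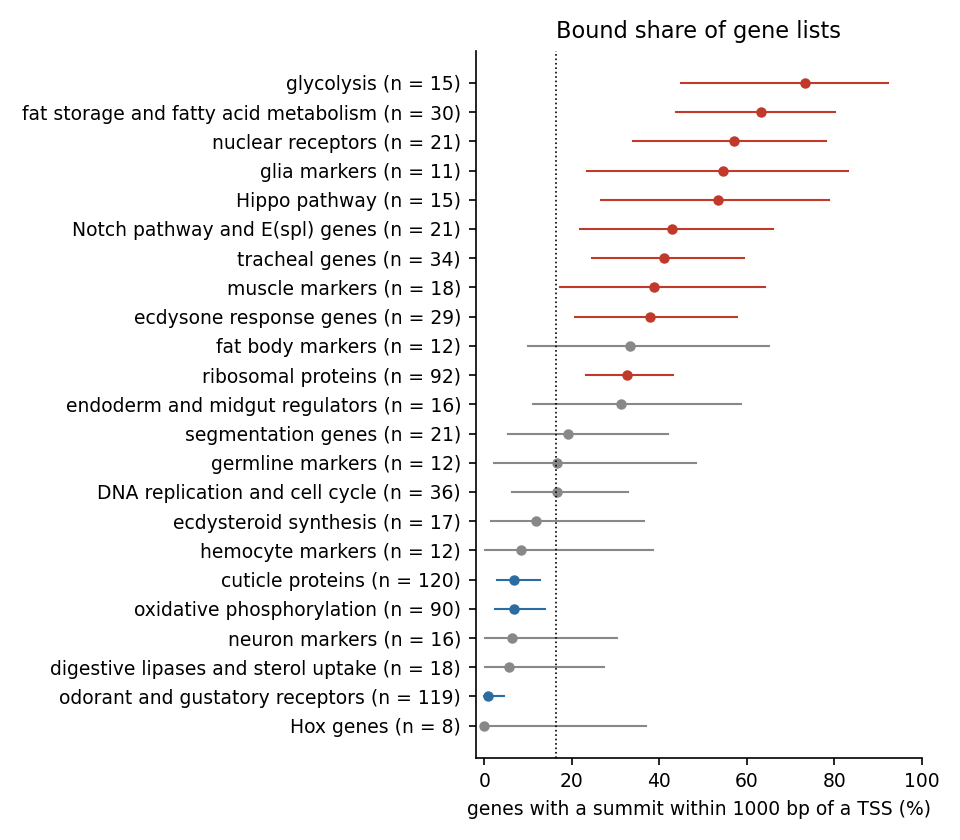
Percent of each list's genes with an optimal summit within 1000 bp of a start site, with 95% exact intervals and list sizes. Red lists were higher and blue lists lower than other genes at an adjusted p below 0.05, grey lists were not called, and the dotted line is the 16.5% of all 13945 genes.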

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

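The lower-ranked peaks were counted after the optimal list had been analysed, and the test of their explanation was fixed before its result was seen. The pooled list held 24277 peaks that are not in the optimal list and enter none of the comparisons above. Of these, 1202 had AGGTCA within 50 bp of the summit, 4.95% (95% exact interval 4.68 to 5.23), against 2.02% of windows 500 bp downstream (exact McNemar test, p = 1.41e-71). These peaks stood out because a signal of the motif appears in data outside the main measurement, at a lower level than the 10.03% of the optimal list. Side summits of optimal regions are a candidate explanation, and they would leave no excess far from those regions. Among 19280 lower-ranked summits more than 1000 bp from every optimal region, the share was 5.08%, against 1.97% in flanks (exact McNemar test, p = 3.70e-64), which argues against side summits as the whole cause. Weak true sites, and sites bound in few cells of the embryo, stay open, and no biological explanation was tested.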

How the results depend on the processing

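Alternatives with 1 summit per region, without higher-coordinate summits of close pairs, with placement or arm length over the stretch spanned by peaks, with nearest replicate summits, without Cpr, without Gpdh1 and Gpo1, and matched on number of start sites were added after seeing the data. Of the comparisons' main values and counts under alternatives, 68 kept direction and side of the threshold (or stayed within their error), 11 moved and 3 lost their call. Of the values for single location classes, motifs, arrangements and lists, 482 kept theirs, 37 lost a call, 27 gained one and 5 reversed. The 5723 highest peaks of the pooled list are the optimal list itself, so that alternative tests nothing. Its values are nevertheless included in the counts of those kept, which are inflated by it. Unless stated, the cause was not tested.

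With only the highest 2861 peaks, Spearman's rho was 0.841, the X ratio 0.916 (permutation p = 0.0739), and the other motifs called numbered 2 instead of 4. The ribosomal protein list was then at 7.61% against 9.96% of other genes, a difference that was not called (Fisher adjusted p = 0.810). The nearest replicate summit within 200 bp gave a rho of 0.736. The X ratio was 0.931 (permutation p = 0.0569) without the higher-coordinate summits of close pairs and 0.988 for peaks more than 500 bp from a start site (0.890 on the stretch spanned by peaks). Other motifs called numbered 2 with 1 summit per region, 2 without those higher-coordinate summits, 2 with upstream flanks, 10 against dinucleotide-shuffled windows and 10 with windows of 100 bp. With AGGTCA in place of RGKTCA, 1 arrangement was called, and DR0, DR2 and DR3 had 0 summit windows, since fewer sequences match. Of the 23 lists, 6 were called against random lists matched on gene length and 5 with start sites also matched. In the latter, muscle markers at 38.9% were below the random mean of 40.1%.

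With each replicate left out in turn, the start-site share was 37.3 to 39.3%, the X ratio 0.861 to 0.926, the AGGTCA share 9.66 to 10.01% and its difference between the 1430 highest and 1430 lowest peaks 4.90 to 7.06 points. Arrangements called numbered 5 to 6 (DR3 was lost in both cases, and DR6 called without replicate 1), other motifs 6 in both cases and gene lists 13 to 14, and the log10 difference between peaks near and away from start sites was 0.0224 to 0.0462. The lower of these last values came without replicate 1. Depth is unknown, so nothing can be said of how it limits these results.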

Other observations

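The tests of description words, gene classes, sequences of 6 bases, lower-ranked peak locations, the order of signals and the AGGTCA share in close pairs of summits, draws of all gene lists, and X density near against away from start sites were chosen after the results were seen. Among words in gene descriptions, genes described as a kinase were bound more often, and genes described as a receptor, many of them chemoreceptors, less often. Of 6994 genes with a description, 228 words were tested. Of 163 genes described as a kinase, 52 were bound (31.9%, against 19.7% of the others, Fisher's exact adjusted p = 0.0142), among them Akt and Alk. Of 322 receptor genes 20 were bound (6.21% against 20.6%, Fisher's exact adjusted p = 4.28e-10), including EcR, Egfr and Ddr. The count includes chemoreceptors: 0 of 70 gustatory genes, 1 of 61 ionotropic genes (Ir94h) and 1 of 60 odorant genes (Or88a) were bound (Fisher's exact adjusted p = 2.52e-05, 0.00249 and 0.00309). These were the 5 words that passed. The word tests were not matched on gene length or number of start sites, and receptors other than chemoreceptors were not tested apart. Among classes of genes, 38 of 290 tRNA genes had a summit within 500 bp of their start (13.1%, 9.44 to 17.5), near the 13.04% of protein-coding genes (12.5 to 13.6). For snoRNA genes it was 10 of 269 (3.72%, 1.80 to 6.73), for other non-coding RNA genes 7.91% (7.01 to 8.89) and for snRNA genes 4 of 32.

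Counting every sequence of 6 bases gave a wider view of the summit windows. Of 2080 such sequences, 150 were more frequent at summits than in flanks and 169 less (exact McNemar tests, adjusted). AGGTCA ranked first by p and GGGTCA next, with 552 peaks against 142 flanks, followed by GGTCAA (564 against 202) and GACCCC (370 against 105). GGTCAA overlaps AGGTCA, and GACCCC, which is GGGGTC on the other strand, overlaps GGGTCA. Such sequences are therefore not separate signals. CTTATC, which holds a GATA core on the other strand, was in 523 against 310. CCAGGA (59 against 171) and AAGGAG (114 against 255) were less frequent at summits. Peaks below the optimal list lay within 500 bp of a start site in 24.2% of cases and in coding sequence in 1.98%.

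Most optimal peaks lack AGGTCA within 50 bp of the summit. If summits were only misplaced, wider windows should show AGGTCA in most peaks. Within 200 bp of the summit 22.3% of peaks had it, against 10.75% of windows of the same width centred 1000 bp downstream. The excess was 11.6 percentage points (10.2 to 12.9), far under the 50 points set before the result was seen. The degenerate form tested, RGKTCA within 50 bp, is likewise not enough, with an excess of 18.2 points (16.8 to 19.7), while other degenerate forms were not measured against that bound and stay open. The part of the pattern that does lie to one side may come from displaced copies of summits toward higher coordinates, since the higher-coordinate summits of close pairs carried AGGTCA in 5.21% of cases, against a mean of 9.69% in 10000 sets of other optimal summits matched on signal decile (permutation p = 2e-04, the smallest possible). Pairs of bound sites have no reason to be ordered along the reference coordinate, yet in 99.3% of the 844 pairs the lower summit had the higher signal (98.5 to 99.7), while binding through other proteins or open chromatin was not tested.

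Glycolysis and fat metabolism genes, taken up because they had the highest bound shares of the 23 lists, were bound in 11 of 15 and 19 of 30 cases. All 23 lists were drawn at random 10000 times, matched on length decile and number of start sites, and the highest standardised excess of any list reached that of the glycolysis genes in 1.60% of draws and that of the fat metabolism genes in 0.06%, which argues against number of start sites and gene length as the whole cause. This was not particular to metabolic genes. In the same draws the figure was 0.03% for the ribosomal protein list and 0.42% for the Notch list. Nuclear receptors came next, at 9.40%. Open promoters of active genes are a possible explanation that cannot be told apart from specific binding here. AGGTCA lay at 5 of the 52 peaks of these genes (9.62%, 95% exact interval 3.196 to 21.0) and at 8.34% of other peaks near start sites (Fisher's exact p = 0.619), too few to decide. Expression in these embryos was not analysed here, so binding stays a hypothesis for regulation of these genes.

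At ribosomal protein genes, 3 of 31 peaks had AGGTCA (9.68%, 2.04 to 25.8), against 8.35% of other peaks near start sites (Fisher's exact p = 0.741). Fewer X copies in embryos of both sexes are a candidate explanation for the lower peak density on X, and would also lower signal there. The median signal of pooled peaks on X was 0.935 times that on the autosomes (permutation p = 1e-04, the smallest possible). The density ratio of optimal peaks away from start sites was 0.988 on whole arm lengths and 0.890 on the stretch spanned by peaks. Near start sites it was lower, at 0.769 and 0.693. Annotated start sites were also less dense on X, so copy number and start-site density cannot be told apart here.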
